A study of Danio rerio with 6 samples.

How the data were processed

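Whole-embryo RNA from 6 pools of 20 zebrafish embryos was measured on 6 one-colour (Cy3) Agilent arrays, 3 for controls and 3 for GLUT2 morphants, with 200 ng of RNA in each labelling reaction. Groups and replicate numbers were taken from the sample titles. The pools are called biological replicates in the labels, which do not say whether they came from separate clutches, so p-values measure the spread between these pools.

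Spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes, which gave background-subtracted and detrended signals within each array and no normalization between arrays. The deposited log2 values of the series table equal the log2 of the background-subtracted signal to within 5e-07 and are empty where that signal is 0 or below. Their scale was thereby known, they were not centred, and their medians were 7.95, 8.63 and 8.16 for controls 1 to 3 and 8.33, 7.87 and 9.22 for morphants 1 to 3. They were used as an alternative.

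Processed signals were put on the log2 scale and each array's percentile 75 over non-control probes was subtracted. Spots marked as non-uniform or population outliers were left out, which left 330 tested probes with a missing value, and saturated spots were kept. Of 43803 non-control probes, the 25829 well above background on all 3 arrays of at least 1 group were tested, and 20404 probes were well above background on all 6. Where a probe was above background on every array of one group and none of the other, the fold is a lower bound, set against the lowest signal above background on each dim array or the probe's own signal where higher. The median negative control signal was 5.29, 20.9 and 4.19 on controls 1 to 3 and 9.20, 4.77 and 61.7 on morphants 1 to 3, so that dim probes were measured less well on morphant 3.

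The arrays were named through RefSeq accessions matched to the gene table of assembly GRCz12tu, used for names alone. Of 34843 accessions 5963 matched, which named 9104 probes (20.8%) and left 34699 unnamed. The gene slc2a2 was not among the names matched.

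Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the one term, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot go below 0.1. A fold change is a difference of mean normalized log2 signals. Of 34 gene lists fixed before the data were examined, the 33 with at least 5 measured members were tested with camera at a preset correlation of 0.01, on the brightest probe of each gene, and 7 passed. With an estimated correlation 0 lists passed, and 1 passed with fry. The estimate was 0.75 for lens, 0.47 for exocrine pancreas, 0.39 for photoreceptors and 0.17 for leukocytes. It was 0.06 for fasting and glucose sensing, 0.05 for cell cycle and -0.03 for cholesterol synthesis. By the rule fixed before the data were examined, the named genes were the largest 8 rises and 8 falls among gene-named probes, taking the brightest probe of each gene, that passed, were separated between groups and were above background on all 6 arrays, up to 3 per direction seen in one group alone, up to 4 members of each called list and up to 2 passing members of each other list. Among falls, only efnb3b and cd99l2 met the criteria for the largest 8. Other genes in the text were chosen after their values were seen, and they illustrate a list.

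The files name 2 slides of 3 arrays, and the 2 scans divide the arrays in the same way, so a single fit with slide as a block stands for both. Across groups, correlations averaged 0.973 on the same slide and 0.961 on different slides. Correlations lay between 0.979 and 0.989 among controls and between 0.962 and 0.973 among morphants. The first 3 principal components held 42.1%, 26.5% and 16.4% of the variance.

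The fit was tested on simulated data for the comparison of morphants with controls, with 25829 probes of which 200 were changed. Of probes changed 2-fold 53% were recovered and of those changed 4-fold 91%, 6 unchanged probes were called, and a shifted gene list was recovered with 0 other lists called. The simulated values were drawn independently for each probe and array, with equal spread on all 6 arrays and no slide effect. They therefore cannot show false calls that come from correlated genes, slide or unequal arrays. The alternatives covered background correction, normalization, the filter, spots left out, the deposited table, slide and replicate blocks, variance moderation, array weights, thresholds, set tests and leaving out each array. Normexp with an offset of 50 was run on median spot signals, as a mean signal column was not used here, and this, the shifted series table, the slide block with the stricter filter and the leukocyte list without socs3a and socs3b were chosen after seeing the data. Figures were drawn in Python 3.11.15.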

Results

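Whole zebrafish embryos were profiled after knock-down of GLUT2, the facilitative glucose transporter encoded by slc2a2. Embryos of the morphant group had received 3.1 ng of a morpholino, an antisense oligonucleotide, that blocks translation of the GLUT2 mRNA, and embryos of the control group a standard control morpholino whose dose the labels do not give. Each group had 3 arrays, and each array measured RNA from a pool of 20 embryos described as a biological replicate. The protocol and the design text put the harvest at 72 hours post fertilization, whereas the sample characteristics give 24 hours. In the control group, 5 of the 12 exocrine pancreas genes on the array, 15 of 32 photoreceptor genes, 6 of 14 intestine genes, 18 of 21 liver genes and 5 of 6 hatching gland genes were well above background on all 3 arrays. The share of the 43803 probes well above background was 72.5%, 60.3% and 76.6% on control arrays 1 to 3 and 67.6%, 72.7% and 47.7% on morphant arrays 1 to 3, and the number of arrays limits the precision.

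The comparison asked which transcripts differ in level between GLUT2 morphants and controls. Transcripts of ttr, a carrier of thyroid hormone, ctsll, a cathepsin L-like protease, and the fast muscle troponin gene tnnc2.1 were higher in morphants, and csrp3, which encodes a muscle LIM protein, and efnb3b, which encodes an ephrin ligand of neural guidance, were lower. The rise was 3.28 ± 0.41 (SE, n = 3 arrays per group) on the log2 scale for ttr, 2.64 ± 0.30 for ctsll and 1.96 ± 0.15 for tnnc2.1, and the limma adjusted p was 0.0380, 0.0335 and 0.0212 in that order. The log2 change was -1.37 ± 0.18 for csrp3 and -1.10 ± 0.14 for efnb3b, with limma adjusted p of 0.0458 for both. For ttr only 1 of the 3 control arrays was well above background, so its change was measured against a group mostly at background, and csrp3 was well above background on 2 of the 3 morphant arrays. Among 25829 tested probes, 60 rose and 51 fell, of which 22 and 9 carried a gene symbol. No probe could be tied to slc2a2 by the names used here, so the targeted gene was not analysed here, and a morpholino that blocks translation need not lower its target's mRNA.

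Several further named genes rose. Transcripts of hspbp1, a co-chaperone that binds HSP70, were well above background on all 3 morphant arrays and on no control array, which put them at least 7.29-fold higher (limma adjusted p = 0.0276). The deacetylase gene hdac10 rose by 2.07, the mitochondrial metaxin gene mtx1b by 1.51, dram1, which acts in autophagy, by 1.48, ankrd9 by 1.48, socs1a, a feedback inhibitor of cytokine signalling, by 1.46, ms4a17a.5 by 1.46 and the troponin I gene tnni1b by 1.34 on the log2 scale, with limma adjusted p between 0.0212 and 0.0375. A further probe of ankrd9 gave 1.3 and one of dram1 gave 1.76. Apart from these genes and cd99l2, the named genes past the threshold rest on a single tested probe. The surface glycoprotein gene cd99l2 fell by 1.31 on the log2 scale (limma adjusted p = 0.0276), and a further probe gave -1.26. For all 111 called probes the 3 morphant arrays lay wholly above or below the 3 control arrays, which held for 25.9% of all tested probes against 10% by chance. With 3 arrays per group a call nearly requires such separation, so it adds no separate support to the calls.

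**Figure D1:**
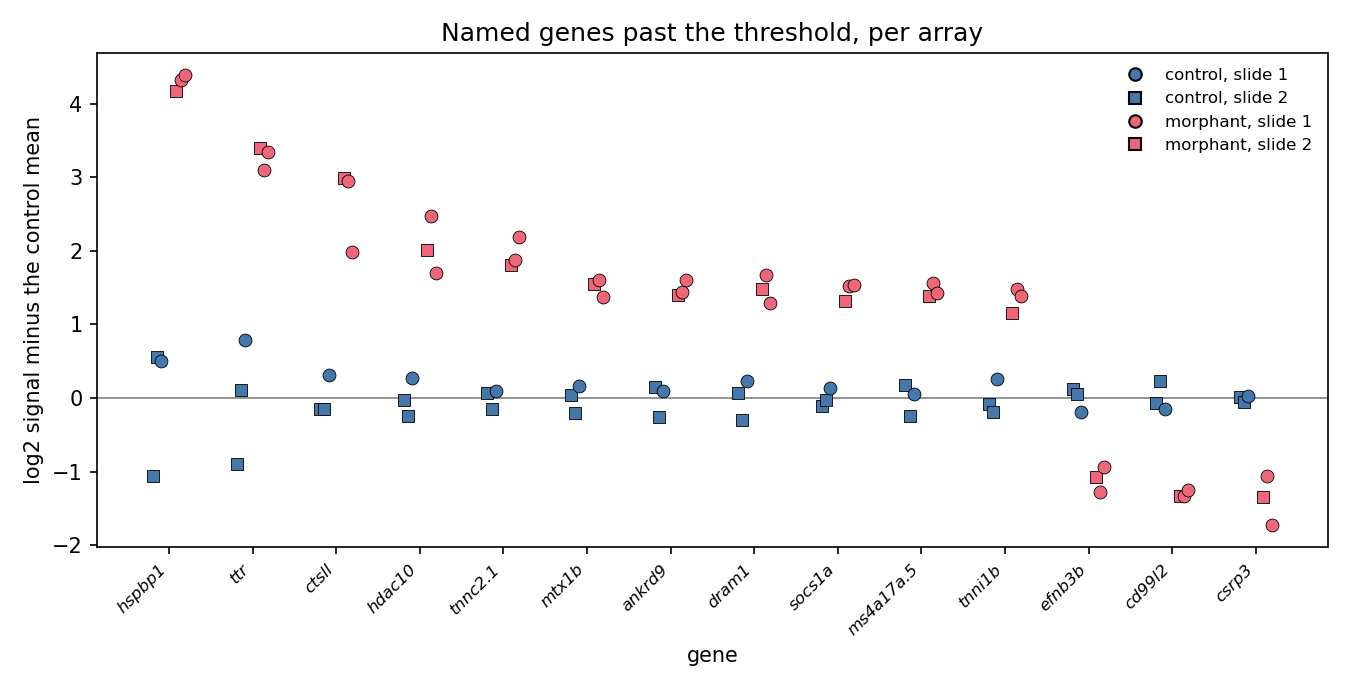
Log2 signal minus the control mean (vertical axis) on each of the 6 arrays for the 14 named genes past the threshold, with control arrays in blue, morphant arrays in red, circles for slide 1 and squares for slide 2. The 3 morphant arrays lie apart from the 3 control arrays for each gene, from hspbp1, whose control arrays were not well above background and which was at least 7.29-fold higher, to csrp3 with a log2 change of -1.37.

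The number of probe calls depended on whether slide was in the fit and on single arrays. A block, like leaving out an array, also leaves fewer degrees of freedom to estimate the spread. A loss of calls alone therefore does not show a slide effect. Slide 1 held control 3, morphant 2 and morphant 3, and slide 2 held control 1, control 2 and morphant 1. With slide as a block 4 probes were higher and 2 lower, and none of the 14 named genes stayed past the threshold. The size of the change moved little (ttr 3.11, ctsll 2.65, csrp3 -1.37). Changes within slides 1 and 2 were 2.43 and 3.80 for ttr, 2.16 and 3.14 for ctsll, and -1.42 and -1.33 for csrp3. As the groups did not overlap for these 14 genes, the direction within each slide was fixed beforehand and adds no separate support. With slide as a block and only probes well above background on all 6 arrays, a setting chosen after seeing the data, 58 were higher and 15 lower. Without morphant 3, the array with the fewest probes above background, 488 probes were higher and 300 lower, and these held all 111, whereas leaving out any other array left between 1 and 9 calls. Normexp background correction gave 99 higher and 37 lower and quantile normalization 45 and 21, so that 72.8% and 68.2% of calls were higher against 54.1% as reported.

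Photoreceptor genes rose together in the morphants. Their median change was 0.77 on the log2 scale over 20 measured members, 19 of which were above 0, and camera gave an adjusted p of 9.66e-07, or 0.562 with an estimated correlation. Of the 20, 10 were higher with p adjusted over the list alone, and none was when adjusted over all probes. The ultraviolet cone opsin gene opn1sw1 had a log2 change of 2.05, the cone kinase gene grk7a 1.66, the cone arrestin gene arr3a 1.45 and the cone transducin gene gnat2 1.21, with grk7a well above background on 2 of the 3 control arrays. The median was 0.76 within slide 1, 0.51 within slide 2 and 0.63 with slide as a block, and 0.51 over the 13 members well above background on all 6 arrays.

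Lens genes fell in the same embryos, with a median of -0.93 over 12 members, 11 of them below 0. Camera gave an adjusted p of 0.00352, or 0.684 with an estimated correlation. With p adjusted over all probes no member passed, and over the list alone 1 was lower. That member was the beta crystallin gene cryba2b, with a log2 change of -1.74, and the gamma crystallin genes crygm3, crygm2d13 and crygm2d8 stood at -1.41, -0.999 and -0.88 without passing, crygm3 with 1 of 3 morphant arrays well above background. The lens median was -0.68 with slide as a block, -1.29 within slide 1 and 0.06 within slide 2, where morphant 1 lay at 0.15 against the control mean, while morphants 2 and 3 lay at -1.57 and -0.95. Without control 1 the camera adjusted p for the lens was 0.0513 and without morphant 3 it was 0.0773, with a median of -0.48. With no filter on dim probes the lens median was -0.30 over 22 members, at a camera adjusted p of 0.0877.

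Genes of the exocrine pancreas, which makes digestive enzymes, had the highest median of any called list, 1.42 over 7 members, 5 above 0. Camera gave an adjusted p of 0.0479, or 0.684 with an estimated correlation. With p adjusted over all probes no member passed. Over the list alone 2 were higher, the trypsin-like protease gene prss59.1 at 3.14 and the chymotrypsinogen gene ctrb.1 at 2.03. The elastase gene cela1.6 stood at 1.81 and the carboxypeptidase gene cpa4 at 1.42 without passing, and the amylase gene amy2al1 at -0.45. The prss59.1 and cpa4 probes were well above background on 2 of the 3 control arrays and amy2al1 on 2 of the 3 morphant arrays. The spread between morphant arrays was wide, with medians against the control mean of 1.07, 0.25 and 2.24 for morphants 1 to 3, and control 3 at 0.57. With slide as a block the adjusted p was 0.0935 at a median of 1.31, the medians within slides 1 and 2 were 0.83 and 1.36, and without morphant 3 the median was 0.71. The list passed in 6 of 20 alternative settings.

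**Figure D2:**
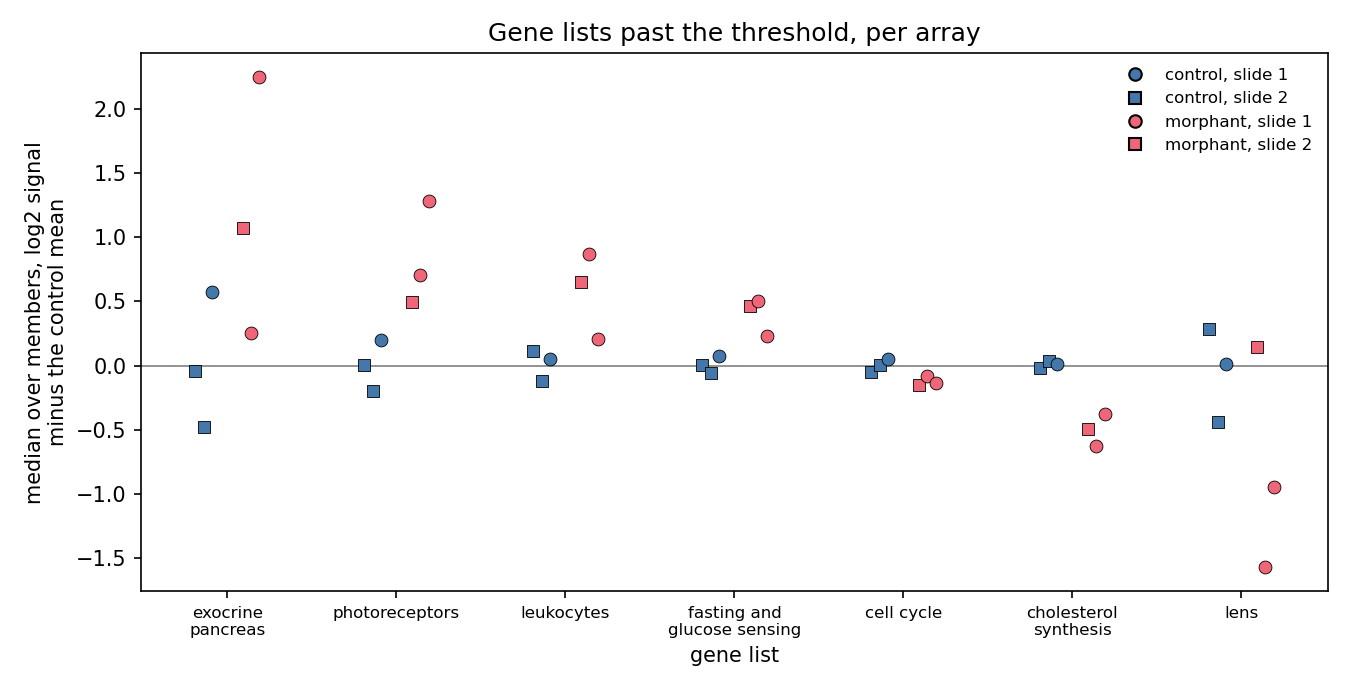
Median over the members of each of the 7 called gene lists of the log2 signal minus the control mean (vertical axis), 1 point per array, with control arrays in blue, morphant arrays in red, circles for slide 1 and squares for slide 2. Photoreceptor medians of the morphants run from 0.50 to 1.28, and the lens median of morphant 1 is 0.15 while those of morphants 2 and 3 are -1.57 and -0.95.

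Leukocyte genes rose with a median of 0.64 over 14 members, 12 above 0 (camera adjusted p = 0.000208, or 0.562 with an estimated correlation). With p adjusted over all probes no member passed. With p adjusted over the list alone 8 members were higher and none lower. They included socs3a at 1.19, socs3b at 0.85, the chemokine receptor gene cxcr3.2 at 1.04 and the macrophage perforin gene mpeg1.1 at 0.77 on the log2 scale. The cxcr3.2 probe was well above background on 2 of the 3 control arrays and a further one gave 0.21, and the neutrophil lysozyme gene lyz stood at 0.18 without passing. As socs3a and socs3b respond to cytokines in many cell types, the list was also tested without them, which gave a median of 0.60 and a camera adjusted p of 0.00515. The median within slides 1 and 2 was 0.54 and 0.66, and 0.63 with slide as a block. Against the control mean, the medians were 0.65, 0.87 and 0.205 for morphants 1 to 3, and control 1 lay at 0.11.

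Genes of cholesterol synthesis fell, with a median of -0.46 over 10 members, 8 of them below 0. Camera gave an adjusted p of 0.00515, or 0.562 with an estimated correlation, and this was the one list past the threshold with fry, a self-contained set test, at an adjusted p of 0.0141. Its estimated correlation was -0.03, below the preset 0.01, so correlation among members does not account for the higher camera p. With p adjusted over all probes no member passed. Over the list alone 4 members were lower, namely cyp51, sc5d, ebp and mvda, at -0.98, -0.70, -0.67 and -0.48. The cyp51 probe was well above background on 2 of the 3 morphant arrays. The further probe of ebp gave -0.32 and that of sc5d -1.01, and insig1, which restrains the pathway, stood at 0.48 without passing. The median was -0.41 and -0.50 within slides 1 and 2 and -0.45 with slide as a block, and the camera adjusted p was 0.0773 without morphant 3.

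Genes of fasting and glucose sensing rose by a median of 0.33 over 15 members, 12 above 0 (camera adjusted p = 0.00946, or 0.562 with an estimated correlation). With p adjusted over all probes no member passed. Over the list alone 1 did, igfbp1a, a binding protein for insulin-like growth factors, at 0.66. The arrestin-domain genes arrdc3b and arrdc2 stood at 0.88 and 0.71 and txnipa, whose product restrains glucose uptake, at 0.58. The median was 0.13 and 0.48 within slides 1 and 2 and 0.30 with slide as a block, and the camera adjusted p was 0.0652 without morphant 1 at a median of 0.24. Without control 1 the median was 0.21 and the list still passed (camera adjusted p = 0.0169). Cell cycle genes fell by a median of 0.17 on the log2 scale over 41 members, 30 of them below 0 (camera adjusted p = 0.0161, or 0.562 with an estimated correlation). None of the 41 passed over the list alone, and plk1, ccnd1, ccne2 and pole2 stood at -0.50, -0.46, -0.38 and -0.37. The cell cycle median was -0.18 and -0.17 within slides 1 and 2 and -0.18 with slide as a block, and the camera adjusted p was 0.0595 without control 3.

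**Figure D3:**
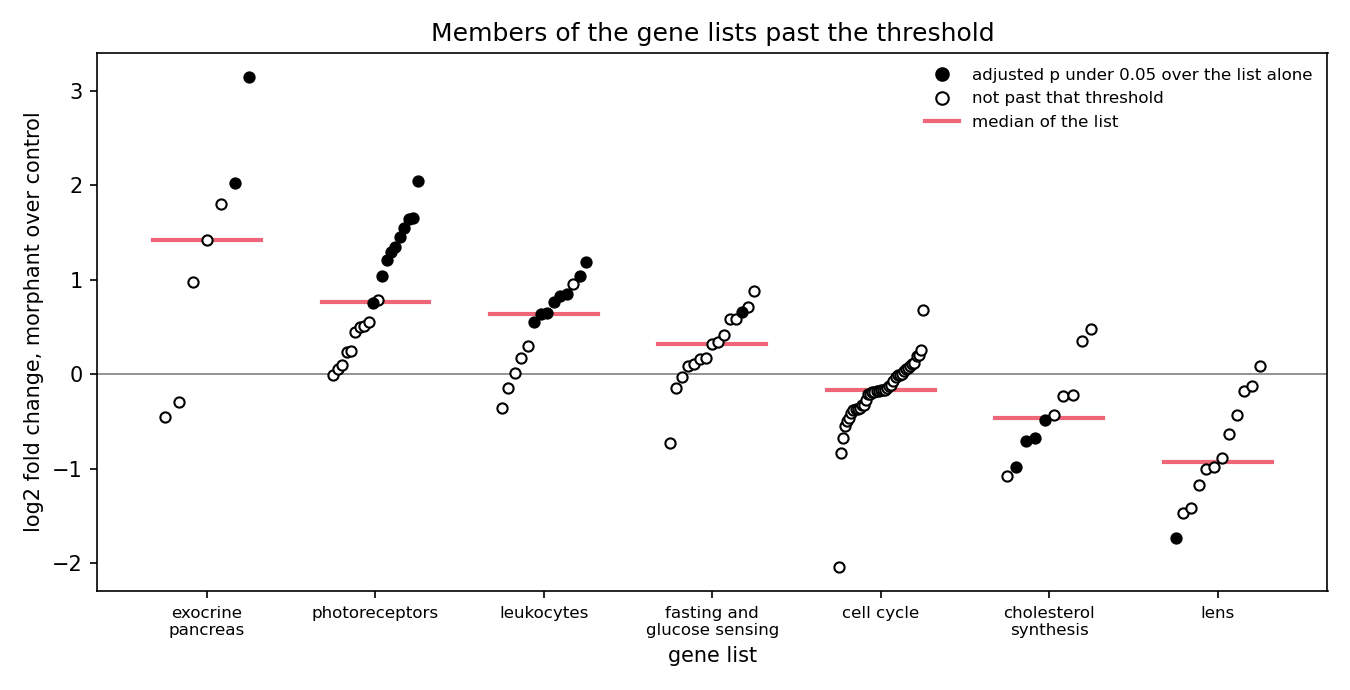
Log2 fold change of morphant over control (vertical axis) for each measured member of the 7 called gene lists, with filled points for members past an adjusted p of 0.05 over the list alone and a red line at the median. In the photoreceptor list 10 of 20 members are filled, in the leukocyte list 8 of 14, and in the cell cycle list none of 41.

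The other 26 tested lists did not pass. Among them were glycolysis with a median of 0.06, gluconeogenesis and glycogen with 0.25, neural progenitors with -0.01, differentiated neurons with 0.06, brain regionalisation with -0.05, endocrine pancreas with -0.20, liver with 0.01, intestine with 0.21, skeletal muscle with 0.05 and heart with -0.26. The p53 and apoptosis list, which covers a known response to morpholinos, had a median of 0.06, and with p adjusted over the list alone rrm2b, tnfrsf1a and gadd45aa were higher at 0.57, 0.60 and 0.61 and tp63 lower at -0.45. Erythrocyte genes had a median of -0.20, with hbba1 and urod lower over the list alone at -2.63 and -0.68 and aqp1a.1 higher at 0.46. The hbba1 probe was well above background on 2 of the 3 morphant arrays. No member of the p53 and apoptosis list or the erythrocyte list passed with p adjusted over all probes. Of the glucose transporter list 4 members were measured, too few for the test, and slc2a3a, slc2a12, slc5a11 and slc2a8 stood at 0.08, 0.36, -0.44 and -1.35 without passing, with slc5a11 well above background on 2 and slc2a8 on 1 of the 3 morphant arrays. The remaining lists ranged from endothelium with a median of -0.43 and hatching gland with -0.23 to oxidative stress with 0.15 and heat shock with 0.11. Further medians were -0.18 for cartilage and bone, -0.14 for chaperones of the endoplasmic reticulum, -0.06 for kidney, -0.01 for epidermis, 0.01 for hypoxia, 0.05 for pigment cells, 0.07 for the integrated stress response, 0.07 for fatty acid oxidation, 0.09 for myelin and glia and 0.10 for the circadian clock.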

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

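The 42 named genes kept their direction under every setting run. They were chosen for large changes in these same data, so their constant direction adds little support. Sizes moved, over the settings from 1.66 to 3.93 for ttr and -1.53 to -0.70 for csrp3. For hspbp1 the log2 change ran from 1.73 to 4.98. Its low end lies under the bound of 7.29-fold, 2.87 on the log2 scale, which holds for the processing as reported. For ttr and csrp3 the smallest sizes came from normexp, whose offset shrinks the change of dim probes by construction. Deviations of same-numbered control and morphant arrays correlated at 0.126, -0.166 and 0.215, and only the arrays numbered 2 lay on different slides. Over all control and morphant pairs, correlations ran from 0.126 to 0.275 on the same slide and from -0.423 to 0.0443 on different slides. Pairs on the same slide with different numbers, control 2 with morphant 1 and control 3 with morphant 2, gave 0.275 and 0.153. The values thus followed slide and not replicate number. Each array enters several pairs, so the values are not independent. With the replicate block limma called 1 probe higher and 0 lower, with 4677 at an unadjusted p under 0.05, and the lists stayed at 4 higher and 3 lower. The cause of the shifts below was not tested unless stated.

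Probes higher and lower, reported as 60 and 51, numbered 4 and 2 with slide as a block, 0 and 0 with no filter on dim probes (4016 of 43803 at an unadjusted p under 0.05), 222 and 86 above background on all 6 arrays, 205 and 174 with array weights, 243 and 118 with trend and robust moderation, 23 and 15 with a minimum fold of 1.2, and 1 and 0 at an adjusted p of 0.01. Normexp gave 99 higher, quantile normalization 21 lower, and slide block with the stricter filter 58 higher and 15 lower. The deposited table gave 0 and 0 (2981 at an unadjusted p under 0.05), or 39 and 28 after the percentile shift. Leaving out 1 array gave 1 to 488 higher and 0 to 300 lower, both maxima without morphant 3. Of the calls, 64 were shared with those of the stricter filter (308), 63 with quantile normalization (66) and 111 with array weights (379).

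Lists numbered 0 higher and 0 lower by camera with an estimated correlation, and 0 and 1 by fry. Medians are as reported under both, 0.77 for photoreceptors, 0.64 for leukocytes, 0.33 for fasting and glucose sensing, 1.42 for exocrine pancreas, -0.93 for lens, -0.17 for cell cycle and -0.46 for cholesterol synthesis, the last past the threshold with fry. Leaving out 1 array gave 2 to 4 lists higher, and medians of 0.71 to 2.06 for exocrine pancreas, -1.25 to -0.48 for lens, -0.22 to -0.12 for cell cycle, 0.21 to 0.41 for fasting and glucose sensing and -0.48 to -0.34 for cholesterol synthesis.

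The exocrine pancreas list missed the threshold at medians of 1.27 with array weights, 1.43 with the detected median, 0.63 with no filter, 0.98 with normexp, 1.47 with quantile normalization, 1.45 and 1.42 with the deposited table before and after the shift, and 1.31 with slide as a block. It also missed the threshold without control 1, control 2, morphant 1 or morphant 3 (camera adjusted p = 0.0509, 0.0995, 0.111 and 0.0773), and passed in 6 of 20 settings. The lens list missed it with no filter at -0.30. The other results were counted once per setting for each named gene and each list not called. Of these counts, 1167 kept their side of the threshold, 138 no longer passed and 28 newly passed. All 138 came from the 14 named genes past the threshold, which each passed in 5 to 10 of 18 or 19 settings. The 1167 were mostly genes and lists that had not passed and still did not. No called list or named gene changed sign, which adds little support as both were chosen for their change in these data. Of the lists not called, 14 had a median that changed sign under some setting, such as heart (-0.52 to 0.14) and hatching gland (-0.90 to 0.30). Values for slc2a2 and a separate scan block were not run. Signal over background limits dim probes, most on morphant 3.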

Other observations

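The tests of slide, of developmental timing and of background on morphant 3 were chosen after the results were seen. The slide criterion was also tightened after its values were known, to require each morphant array to lie beyond each control array of its slide, which moved the exocrine pancreas from excluded to open. The test of morphant 3 was first planned on counts of calls among the brightest probes, which were 0 for each other array left out and so decided nothing.

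Other genes past the limma threshold were picked after their values were seen. The immediate early gene junba was higher on 2 of its 8 probes, by 1.17 and 1.16 on the log2 scale, and ggctb, an enzyme of glutathione turnover, by 1.45 and 1.4. The chemokine gene ccl27a was higher by 2.87, the cytoglobin gene cygb1 by 0.97 and the isoleucyl tRNA synthetase gene iars1 by 1.08. Among falls were the mitochondrial creatine kinase gene ckmt1 at -1.37, whose brightest probe stood at -0.34 without passing, and the kinase gene araf at -1.42. The posterior patterning gene hoxd13a stood at -0.87 and the forkhead gene foxb1b at -0.84, while their brightest probes stood at -0.48 and -0.50 without passing. None of these passed with slide as a block, and ccl27a was well above background on 2 of 3 control arrays and araf, hoxd13a and foxb1b on 2 of 3 morphant arrays. In the liver list, ttr rose and fabp10a stood at 1.36 while the median was 0.01.

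The first pattern is that photoreceptor and exocrine pancreas lists were higher and the lens list lower. A slide effect would leave medians near 0 within slides, and for photoreceptors the smaller of the within-slide medians was 0.51, with each morphant array above each control array of its slide, which argues against slide as the whole cause. For the exocrine pancreas the smaller was 0.83 but morphant 2 lay below control 3, and for the lens it was 0.0590, so slide stays open for both. One overall shift in developmental timing could move both eye lists the same way, and the photoreceptor minus lens difference per array was 1.57 higher in morphants (95% interval -0.25 to 3.39, exact permutation p = 0.1, the smallest possible), which leaves it open. An effect of the knock-down on these organs is a hypothesis and stays untested.

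The second pattern is very large single-probe changes. Among 17 called probes with at least a 4-fold change, probes LOLS11149 and A_15_P106744, which have no gene name here, rose at least 293-fold and at least 266-fold, eif3s6ip, picked after its value was seen and above background on 2 of 3 control arrays, rose by 5.57 on the log2 scale, and one sgcg probe stood at -3.97, with 1 morphant array above background, while its other probe was at 0.00. A sequence variant between clutches or a transcript form read by a single probe may underlie such changes, and other probes of the same gene showed a median share of 0.0649 of the change, but for 2 names, too few to decide. The named genes hspbp1, ttr, ctsll and hdac10 were also among the 17 and had no further tested probe, so this stays open for them. Over all called probes with a further probe, 19 names, the median share was 0.965 and 14 names showed over 0.5.

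The third pattern is that limma called 788 probes without morphant 3 and 111 with it. Raised background on that array could add noise, most to dim probes, and among the 8610 brightest probes limma called 73 without morphant 3 and 0 with all 6 when p was adjusted over these probes alone. At an unadjusted p under 0.05 these bright probes numbered 1514 without morphant 3, 1.31 times the 1153 without morphant 1, the highest of the other arrays left out, which leaves background open. A difference of that pool from the other morphant pools is a hypothesis that was not tested.

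In the 10 splits of the 6 arrays, 1 gave as many higher probes as the real 60 and 1 as many lower as the real 51, the real split itself, and the highest other count was 22. That count came from the split along the slides, which called 28 probes, and with slide as a block 4 probes were higher and 2 lower, while the log2 change of tnnc2.1 was 1.96 without and 1.90 with the block and that of ttr 3.28 and 3.11. For gene lists 2 of the 10 splits gave as many as the real 7, and the highest other was 7. In every split the tested probes were those kept by the filter on the real groups, which can favour the real split. With 10 splits no share under 0.05 can be reached.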
